A study of Homo sapiens with 2 samples.

How the data were processed

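Small RNA was sequenced from SWAN-71 cells, a trophoblast line from an early placenta that was immortalised with telomerase. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum and starved for 4 h in plain DMEM. Treated cells then received hepatocyte growth factor (HGF) at 50 ng/ml for 24 h, and control cells stayed in plain DMEM for the same 24 h. Libraries were made from 1 µg of total RNA with the TruSeq small RNA kit and read on an Illumina Genome Analyzer IIx. Per the series' design text, the authors trimmed adapters and low-quality bases in CLC Genomics Workbench 6.5.1 and mapped the reads to miRBase release 21. How many mismatches were allowed, how reads that match several miRNAs were assigned, and whether strand was used are not given in the sources used here. The genome build is not given either, since reads were compared with miRNA sequences.

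The deposited tables give, for each miRNA and library, a read count, a normalized value in CPM, and for the comparison a signed fold change and a p-value. Read counts are whole numbers of reads per mature miRNA, per the file headers and the values the authors deposited. The normalized values the authors deposited are CPM, counts per 1000000 reads of a library total,, since count divided by deposited CPM gave 1 total per library. The deposited fold change is the signed ratio of the authors' CPM values, HGF over control, with a minus sign for miRNAs lower with HGF. The test behind the authors' deposited p-value is not given in the sources used here. The count and CPM columns are headed with library codes, and those codes are paired with control and HGF by the submitters' name for the table and by nothing else. The title of the only untreated sample ends in a 2, and whether another untreated library was made is not given in the sources used here. Because 1 table lists all miRNAs and a second lists those called different, and both rest on the same 2 libraries, they are not independent.

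The table of all miRNAs has 905 entries. Of these, 13 have 0 reads in both libraries, none has reads in 1 library only, and 892 were read in both. The listed counts sum to 2614540 reads for the control and 1341775 for HGF, a ratio of 1.95. In the HGF library 1 read is worth 0.745 CPM, and in the control 0.382 CPM. A miRNA of few reads is therefore measured less precisely in the HGF library, and 276 entries have under 10 reads over both.

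CPM was recomputed from the deposited counts with the sum of listed miRNA counts as library size. The ratio of HGF over control was taken for each miRNA, with an exact conditional binomial (Clopper-Pearson) 95% interval. A miRNA was counted as 2-fold higher or lower where the ratio reached 2, at least 50 reads were present over both libraries and the interval excluded 1. There is 1 library per group, so no difference has a replicate check and no p-value was computed. The intervals compare these 2 libraries, not the conditions. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The planned count packages were not used, because separator marks within the deposited numbers kept these columns from being entered as counts, and none of the planned measures needs a model.

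Lists of miRNAs, 16 in number, and markers of 6 other cell types were fixed before the data were examined, as were the rule for named miRNAs and the settings to be varied. For each list the median log2 ratio was taken over arms with at least 20 reads. An interval for the median came from 1000 Poisson draws of the counts. For lists with at least 3 such arms, the median was ranked among 10000 random lists of the same size matched on mean abundance in 5 bins. This percentile describes these libraries and is not a test across samples. Members of a list can share a hairpin or lie next to each other, and the random lists do not keep such links. A percentile can therefore look more extreme than it is. The miRNAs named are the 12 highest and the 12 lowest ratios among those with at least 50 reads whose interval excludes 1, the 10 most abundant, and up to 4 of the most abundant members of each list. Other miRNAs are named as chosen after their values were seen.

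The settings varied were TMM factors and median-of-ratios size factors, both computed from their formulas, a total without the most abundant miRNA, a pseudocount of 1 CPM and the authors' deposited fold change. Others were read minimums of 10, 100 and 200 or none, thresholds of 1.5-fold and 4-fold, no interval, arms of a miRNA summed, and the ratio of summed counts for lists. TMM trimmed 30% of the ratios and 5% of the abundances at each end. A further 3 were added after the data were seen, and the closing section names them.

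The calling rule was tested on simulated data for the comparison of HGF with control. In 20 simulations of 892 miRNAs, 200 were changed by a known fold and counts were drawn at the real library sizes. Of miRNAs raised 4-fold with at least 50 reads, 99.6% of 552 were called, and of those raised 3-fold, 87.5% of 488. Of those lowered 4-fold and 3-fold, 100% of 437 and 99.2% of 399 were called. Of unchanged miRNAs, 1.68% of 6180 were called. Counts were Poisson draws from a shared profile, with no PCR variation and none between libraries beyond the set changes. This share is therefore not a false-call rate for real libraries. Changes in abundant miRNAs shifted the shares of all others, by a log2 ratio between -0.65 and -0.04 in each simulation, and calls from this shift were not separated from calls from counting error. The interval held the true ratio of shares in 96.1% of 8056 cases, as an exact interval does for such draws by construction.

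Hairpin coordinates and host genes come from GENCODE release 29 on GRCh38, 1-based, matched by miRNA name, because the deposited tables give none. Of 905 entries, 904 matched a hairpin. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.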

Results

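Mature miRNAs were counted in 2 small RNA libraries of SWAN-71 cells, 1 from untreated control cells and 1 from cells given HGF for 24 h. SWAN-71 is a trophoblast line, and HGF is a growth factor that acts through the receptor tyrosine kinase MET. The comparison asks which miRNAs differ with HGF. The control library held 2614540 listed miRNA reads and the HGF library 1341775. Each value below comes from 1 library per group, so ratios carry counting intervals and no replicate error.

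A few miRNAs made up most of both libraries. The 10 most abundant took 58.3% of control reads and 61.7% of HGF reads. The most abundant was miR-22-3p, from an exon of MIR22HG on chromosome 17 (1713903 to 1713987, GRCh38), with 13.4% of control reads (exact 95% interval 13.3 to 13.4) and 14.03% of HGF reads (13.98 to 14.09). Next came miR-21-5p, widely studied as a growth-associated miRNA, whose hairpin lies in an exon of VMP1 on chromosome 17 (59841266 to 59841337). Its share was 8.86% in control and 9.81% with HGF. The pair miR-10b-5p and miR-10a-5p, from introns of HOXD3 and HOXB3 on chromosomes 2 and 17, took larger shares in the HGF library. miR-10b-5p had 6.93% and 8.54%, a log2 ratio of 0.30 (95% interval 0.29 to 0.31). miR-10a-5p had 4.35% and 5.80%, a log2 ratio of 0.42 (0.40 to 0.43). Lower shares were seen for miR-92a-3p, at a log2 ratio of -0.23 (-0.25 to -0.21), and let-7f-5p, at -0.19 (-0.20 to -0.17). The others lay within 0.1 of no difference: miR-16-5p at 0.02, miR-26a-5p at 0.05, miR-191-5p at -0.02 and let-7a-5p at -0.07. The last 2 were above 0 under TMM scaling, at 0.08 and 0.03.

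HGF and control libraries were alike for most miRNAs. Of 404 miRNAs with at least 50 reads, 317 (78.5%) lay within 1.5-fold. The interval lay above 1 for 54, below 1 for 157 and spanned 1 for 193, and under TMM scaling it lay above 1 for 74 and below 1 for 108. At least 2-fold, 8 were higher and 22 lower with HGF. The balance of directions depends on the minimum of reads: 19 were higher and 32 lower with none, and 5 and 6 with at least 200 reads. The control library is deeper, so at equal mean CPM a miRNA higher with HGF has fewer summed reads than one equally lower. It is therefore left out more readily by such a minimum. The balance also depends on the scaling. TMM factors added 0.10 to every log2 ratio, moved the median of all 404 from -0.16 to -0.06, and gave 11 higher and 15 lower. Each list's median below stands against that median of -0.16. A list's median takes arms with at least 20 reads, while the -0.16 takes miRNAs with at least 50.

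**Figure D1:**
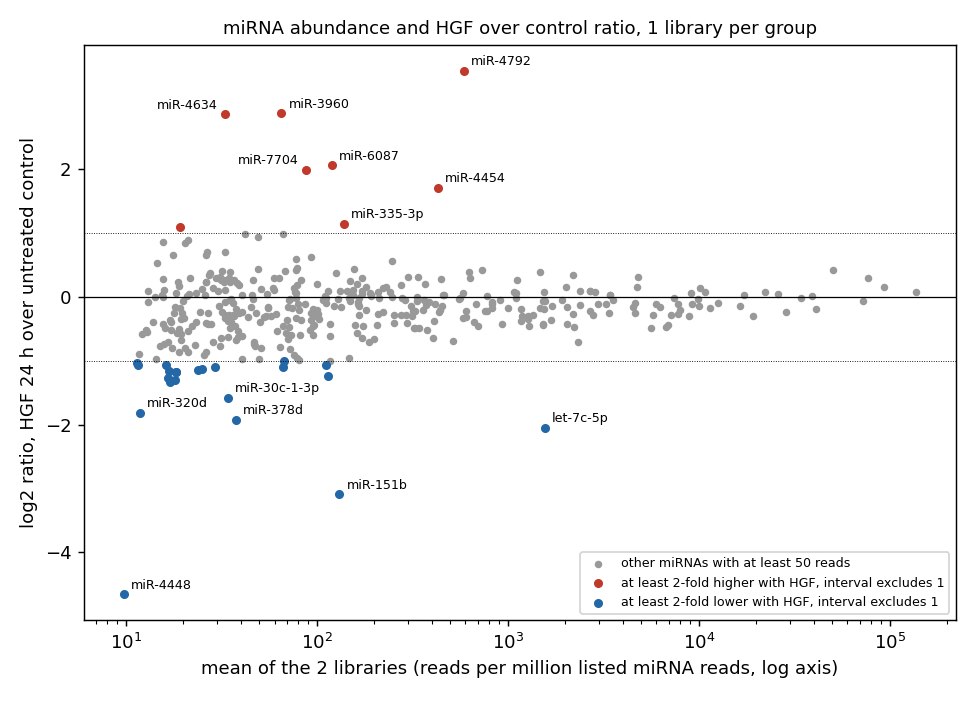
Log2 ratio of HGF 24 h over untreated control (vertical axis) against the mean of both libraries in CPM of listed miRNA reads (horizontal log axis) for 404 miRNAs with at least 50 reads, 1 point each. Red points are the 8 miRNAs at least 2-fold higher and blue points the 22 at least 2-fold lower, with miR-4792 highest at 3.54 and miR-4448 lowest at -4.65.

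The miRNAs highest with HGF against control were led by miR-4792, with 244 reads in control and 1453 with HGF. Its CPM went from 93.3 to 1083, an 11.6-fold ratio (95% interval 10.1 to 13.3). The hairpin lies on chromosome 3 (24521362 to 24521435, minus strand). No host gene was found for it among the gene types searched, on the same strand only. miR-3960 followed, 7.32-fold higher (5.16 to 10.6) with 41 and 154 reads, from an exon of CDK9 on chromosome 9 (127785833 to 127785923). miR-4634, with 21 and 78 reads, was 7.24-fold higher (4.42 to 12.3), and lies in an intron of a non-coding RNA on chromosome 5 (174751734 to 174751787). miR-6087 was 4.17-fold higher (3.35 to 5.22) and miR-7704, in an exon of HOXD1, 3.96-fold (3.07 to 5.14). miR-4454 was 3.27-fold higher (2.93 to 3.65), from 202 to 659 CPM. 6 of the 8 carry no arm in their name, and 5 have hairpins of at least 70% GC, as do 22 of the 403 miRNAs with at least 50 reads and a known hairpin. The other 2 were miR-335-3p, at 2.21-fold (1.84 to 2.65), and miR-503-5p, at 2.13-fold (1.28 to 3.56). miR-335 lies in an intron of the imprinted gene MEST on chromosome 7 (130496111 to 130496204), and miR-503 in an intron of MIR503HG on chromosome X (134546328 to 134546398).

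The 12 highest were completed by miR-1246 at 1.98-fold (1.52 to 2.58), miR-3141 at 1.97-fold (1.41 to 2.76), miR-1908-5p at 1.90-fold (1.401 to 2.59) and miR-33b-5p at 1.85-fold (1.15 to 2.98). The hairpin of miR-1246 shares 18 bases with an annotated copy of U2 small nuclear RNA, from which its reads were not told apart. miR-1908 lies in an exon of FADS1, a fatty acid desaturase, on chromosome 11 (61815161 to 61815240). miR-33b lies in an intron of SREBF1, a regulator of lipid synthesis, on chromosome 17 (17813836 to 17813931).

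The miRNAs lowest with HGF included 6 that share their number with a more abundant miRNA. let-7c-5p was the most abundant of the 12, with 6557 reads in control and 813 with HGF, from 2508 to 606 CPM. It was 4.14-fold lower (3.85 to 4.46), and its hairpin lies in an intron of MIR99AHG on chromosome 21 (16539828 to 16539911). miR-151b was 8.52-fold lower (6.11 to 12.2), with 614 and 37 reads. miR-378d was 3.79-fold lower (2.39 to 6.29), miR-320d 3.52-fold (1.58 to 9.22), miR-30c-1-3p 2.99-fold (1.91 to 4.88) and miR-320c 2.53-fold (1.38 to 5.001). The more abundant relatives differed less: log2 ratios were -0.07 for let-7a-5p, -0.14 for miR-151a-5p, -0.28 for miR-378a-3p, -0.45 for miR-320a and 0.02 for miR-30a-3p. How reads were divided between near-identical miRNAs is not given in the sources used here, so the values of let-7c-5p, miR-151b, miR-378d, miR-320c and miR-320d are uncertain. miR-30c-1-3p and miR-30a-3p were paired by number and arm, not by sequence.

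Among the remaining 6, miR-4448 had 49 reads in control and 1 with HGF, a log2 ratio of -4.65 with an interval from -9.98 to -2.11. miR-222-5p was 2.36-fold lower (1.88 to 2.998) with 419 and 91 reads, and lies in an intron of MIR222HG on chromosome X (45747015 to 45747124). miR-2355-5p, from an intron of KLF7, was 2.46-fold lower (1.37 to 4.73), and miR-6840-5p, from an exon of PILRB, 2.41-fold (1.31 to 4.78). miR-3135b and miR-543 were both 2.26-fold lower (1.28 to 4.26), with 66 and 15 reads each.

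**Figure D2:**
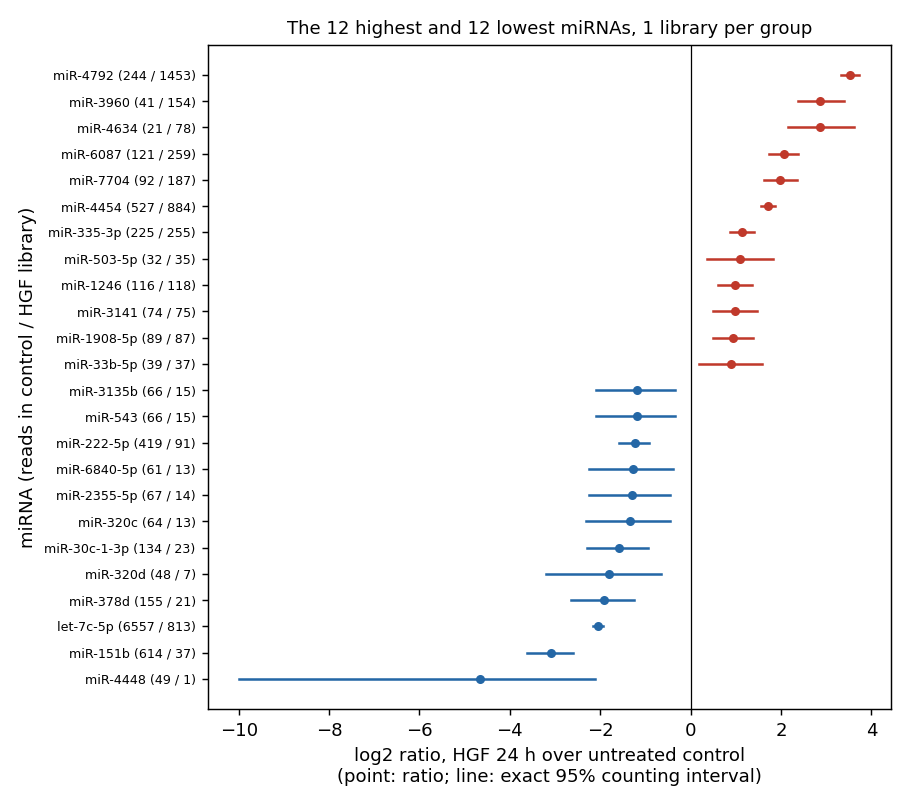
Log2 ratio of HGF 24 h over untreated control (point) with its exact 95% counting interval (line) for the 12 highest and 12 lowest miRNAs, with reads in control and HGF beside each name. The interval is narrow for let-7c-5p (6557 and 813 reads) and wide for miR-4448 (49 and 1 reads).

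The placental clusters differed in whether they were listed at all. None of the 37 members of the chromosome 19 cluster C19MC, a primate-specific group typical of villous trophoblast, had an entry. The library totals implied by the authors' CPM exceed the listed reads by 632 reads in control and 103 with HGF. If those totals hold every miRNA read, all unlisted miRNAs together reach at most 242 and 76.8 CPM as counted. The upper ends of the exact 95% interval were 0.0261% of reads in control and 0.00931% with HGF. The imprinted chromosome 14 cluster C14MC was listed for 46 of 49 members. Over 67 arms, 2 were higher with HGF, 14 lower and 51 had an interval spanning 1, against 3, 7 and 57 under TMM scaling. The median log2 ratio was -0.15, at the 63.5 percentile of random lists. miR-411-5p was higher, at 0.16 (0.11 to 0.20), while miR-654-3p and miR-409-3p were lower, at -0.23 and -0.13. miR-127-3p, the most abundant, was at -0.09 (-0.12 to -0.06) and turned to 0.01 under TMM scaling. Of the cluster of miR-371 to miR-373, 1 arm was read, miR-373-3p, with 15 and 8 reads.

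The miR-34 and miR-449 family, whose miR-34 members are known targets of p53, stood highest of the lists. Of 6 arms, 3 were higher with HGF, none lower, and 3 spanned 1. The median log2 ratio was 0.53, at the 99.6 percentile of random lists, the highest of the 14 lists ranked. Random lists did not keep links between members of a list. miR-34c-5p was at 0.44 (0.20 to 0.68) with 347 and 242 reads, and miR-34a-5p at 0.62 (0.30 to 0.93) with 193 and 152 reads. miR-449c-5p was at 0.84 (0.14 to 1.55), and miR-449a at -0.39 (-1.21 to 0.38). The list of miRNAs reported to target MET had a median of 0.09, at the 98.0 percentile, with 7 of 12 arms higher, 1 lower and 4 spanning 1. It shares 6 arms with the miR-34 and miR-449 family, and the median of the other 6 was 0.05. Its most abundant members were miR-27b-3p at 0.03, miR-199a-3p at 0.08, miR-130a-3p at 0.10 and miR-199a-5p at 0.30 (0.18 to 0.41). miR-199a-3p has the same mature sequence as miR-199b-3p, and reads were divided almost evenly between them.

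The lists lowest with HGF were the miR-23/27/24 clusters and the miR-221 and miR-222 cluster. Of 9 arms of the former, 7 were lower, 1 higher and 1 spanned 1. Their median was -0.362 at the 2.47 percentile, just under the lower end of the 95% range of random lists (-0.360). The log2 ratio of the summed reads of these clusters was -0.13. miR-27a-3p was at -0.47 (-0.50 to -0.43), miR-24-3p at -0.20 and miR-23a-3p at -0.16, while miR-27b-3p was at 0.03. All 4 arms of miR-221 and miR-222 were lower, with a median of -0.36 at the 6.21 percentile. miR-222-3p was at -0.48 (-0.52 to -0.44) and miR-221-3p at -0.18 (-0.21 to -0.15). Under TMM scaling 5 of the 9 and 3 of the 4 arms were lower.

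The growth-promoting miR-17-92 group and the differentiation-linked let-7 family had medians close to that of all miRNAs, 0.07 and 0.04 below it, and inside the 95% range of random lists. Of 15 arms of miR-17-92 and its paralogous clusters, 9 were lower and none higher, with a median of -0.23 at the 14.1 percentile. miR-20a-5p was at -0.30 (-0.39 to -0.21), miR-93-5p at -0.12 and miR-25-3p at -0.02 (-0.06 to 0.01). Of 18 let-7 arms, 12 were lower and none higher, with a median of -0.20 at the 17.4 percentile. let-7i-5p was at -0.21 and miR-98-5p at -0.11. Under TMM scaling 2 arms of each list were higher, with 7 and 10 lower.

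In the clusters of miR-10, miR-99, miR-100 and miR-125, members of different loci went opposite ways. Against the higher miR-10a-5p and miR-10b-5p stood miR-100-5p at -0.45 (-0.49 to -0.41) and miR-99b-5p at -0.30 (-0.33 to -0.27). Of 14 arms, 2 were higher, 6 lower and 6 spanned 1, against 3, 4 and 7 under TMM scaling. The median was -0.24, at the 13.7 percentile, while the log2 ratio of summed reads was 0.24, set by miR-10a and miR-10b. The list of growth factor, AP-1 and NF-kB responsive miRNAs was also split: of 17 arms, 3 were higher, 8 lower and 6 spanned 1. Under TMM scaling these counts were 3, 6 and 8. The median was -0.18 at the 29.9 percentile, and the log2 ratio of summed reads 0.06. miR-22-3p at 0.07, miR-21-5p at 0.15 and miR-146a-5p at 0.13 (0.10 to 0.16) were higher. Lower members included miR-155-5p at -0.71 (-0.78 to -0.65), with 7578 and 2371 reads, named after its value was seen.

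The miR-15/16, miR-30, miR-29 and miR-181 families had medians inside the 95% range of random lists. The miR-15/16 family had a median of -0.04 over 12 arms (2 higher, 2 lower, 8 spanning 1) at the 79.5 percentile, with miR-15b-5p at -0.04, miR-15a-5p at 0.07 and miR-16-2-3p at -0.49. The miR-30 family had -0.06 over 11 arms (2, 4 and 5) at the 73.5 percentile, with miR-30a-5p at 0.08, miR-30e-5p at 0.07, miR-30d-5p at -0.15 and miR-30c-5p at -0.06. The miR-29 family had -0.07 over 6 arms (1, 2 and 3) at the 66.4 percentile, with miR-29a-3p at -0.12, miR-29b-3p at 0.19 and miR-29c-3p at -0.02. All 3 medians were above 0 under TMM scaling, at 0.06, 0.04 and 0.04, and that of miR-15/16 also under median of ratios, at 0.004. The miR-181 family had -0.18 over 9 arms (2, 3 and 4) at the 34.4 percentile, with miR-181a-5p at 0.07 and miR-181b-5p at -0.18. The log2 ratio of its summed reads was 0.01. Under TMM scaling the arms higher, lower and spanning 1 were 1, 0 and 5 for miR-29, 2, 1 and 6 for miR-181, 4, 2 and 6 for miR-15/16, and 2, 3 and 6 for miR-30. The epithelial miR-200 family was scarce: 3 arms, all spanning 1, had a median of 0.26 at the 86.8 percentile. This is 0.42 above the median of all miRNAs with at least 50 reads, a minimum that none of these arms reached. miR-200b-3p had 26 and 16 reads, miR-141-3p 18 and 14, and miR-200c-3p 17 and 9.

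**Figure D3:**
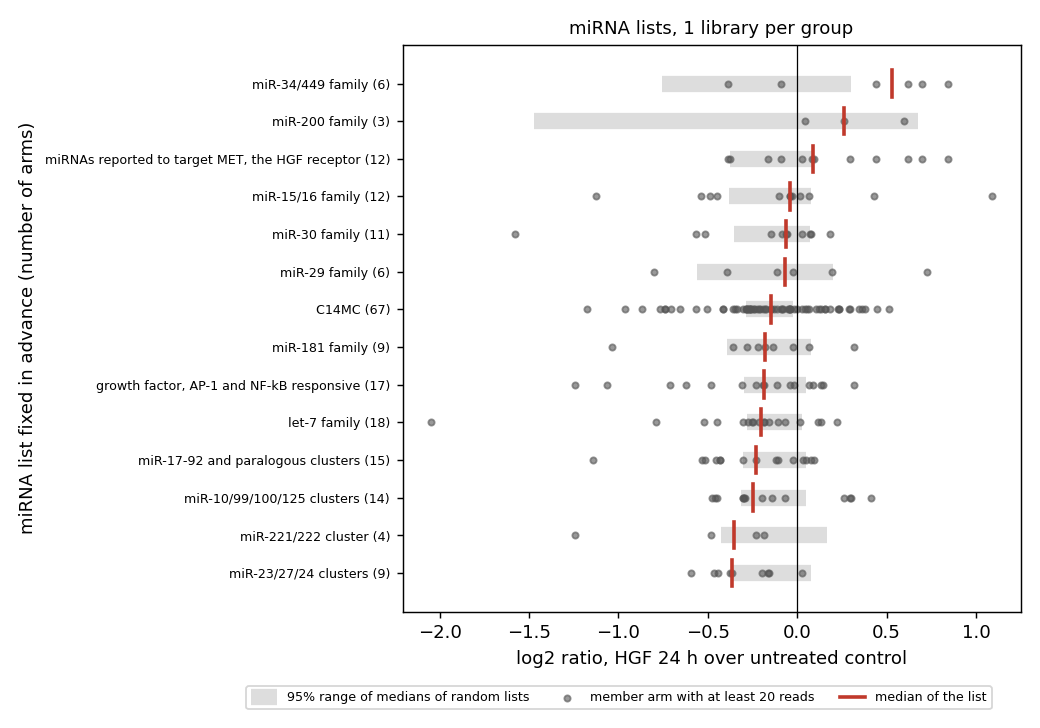
Log2 ratio of HGF 24 h over untreated control (horizontal axis) for arms with at least 20 reads (grey points) of 14 miRNA lists (rows, number of arms in parentheses), with each list's median (red line) and the 95% range of medians of random lists of the same size and abundance (grey band). The median of the miR-34 and miR-449 family, 0.53, lies above its band.

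Markers of other cell types differed in both directions. The blood-associated miR-451a and miR-223 had no entry, miR-142-5p was at 147 and 146 CPM, miR-144-5p had 3 reads in each library and miR-150-5p 1 read in each. miR-486-5p went from 405 to 489 CPM and its other arm miR-486-3p from 23.3 to 10.4. The endothelial miR-126-5p was at 1510 CPM in control and 1590 with HGF, and its other arm miR-126-3p at 212 and 209 CPM. The hepatocyte miR-122-5p had 2 and 4 reads. Of the muscle miRNAs, miR-133a, miR-133b, miR-208a and miR-208b had no entry and miR-499a-5p had 3 and 2 reads. The neuronal miR-124 had no entry, and both arms of miR-9 were higher with HGF, miR-9-5p at a log2 ratio of 0.41 (0.30 to 0.52), from 628 to 836 CPM, and miR-9-3p at 0.86 (0.05 to 1.67). miR-219a-1-3p had 34 and 9 reads, and miR-219a-5p, miR-129-5p and miR-129-2-3p had at most 3 reads per library. Of mesenchymal markers, miR-199a-3p was at 2604 and 2761 CPM, miR-143-3p at 379 and 271, miR-214-3p at 19.5 and 16.4, and miR-145-3p had 3 reads and 1 read.

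The authors' deposited table of differential miRNAs holds 187 entries, 51 higher and 136 lower with HGF. These are all entries of the authors' deposited full table whose p-value was at most 0.05. The table's heading names a fold change of 2, yet 148 of its entries (79.1%) are under 2-fold, and the smallest deposited fold is 1.02. Of the entries in the authors' deposited table, 39 reach 2-fold, 16 higher and 23 lower, and 10 of these have under 50 reads. It holds 28 of the 30 miRNAs that were at least 2-fold by the rule used here.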

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

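Reads outside the listed miRNAs were flagged because no entry of the table holds them. The library totals implied by the deposited CPM exceed the sum of listed counts by 632 reads in the control library and by 103 in the HGF library. These are 0.0242% and 0.00768% of the implied totals. The 3 reads that a count of 0 allows apply to a single entry, so a sum over unlisted entries can pass them easily. The table lists no miRNA read in 1 library only, so entries read in a single library are not analysed here. No explanation of the difference between 632 and 103 was tested, and the control library was sequenced 1.95 times as deeply.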

How the results depend on the processing

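Totals implied by the authors' CPM, same-arm siblings summed, and the list of MET-targeting miRNAs without the miR-34 and miR-449 family were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for that reason no library could be left out. Of 22 miRNAs lower and 8 higher at 2-fold, other settings gave for higher and lower: 19 and 61 at 1.5-fold, 4 and 3 at 4-fold, and 5 and 6 with at least 200 reads. They were 16 and 32 with a minimum of 10 reads, 19 and 32 with none, and 7 and 14 with arms summed. With same-arm siblings summed they were 9 and 17, with median-of-ratios factors 10 and 20, and with the pseudocount 8 and 18. Read minimums, thresholds and summing let fewer or more miRNAs count by construction. The authors' deposited table held 7 higher and 5 lower at 4-fold, against 51 and 136.

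TMM factors add 0.10 to each log2 ratio by construction. They gave medians of -0.042 for C14MC, -0.096 for let-7, 0.065 for miR-15/16, 0.043 for miR-30 (reversed), -0.25 for miR-221 and miR-222 and -0.078 for growth factor, AP-1 and NF-kB responsive miRNAs. They reversed let-7a-5p to 0.034, miR-191-5p to 0.081, miR-127-3p to 0.013 and miR-30c-5p to 0.047. Median-of-ratios factors gave -0.16 for let-7 and -0.31 for miR-221 and miR-222 and reversed miR-191-5p to 0.020. Summed reads, which abundant members set, gave -0.15 for let-7, -0.13 for miR-23/27/24, -0.0063 for miR-30 and -0.28 for miR-221 and miR-222. They reversed miR-181 to 0.0086, miR-10, miR-99, miR-100 and miR-125 to 0.24 and the growth factor list to 0.060. With no minimum beyond 1 read miR-17-92 was at -0.30, where the cause was not tested.

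For lists, 110 of 126 recomputed medians stayed within their counting interval. For the 79 named miRNAs, 404 of 474 recomputed ratios did, 65 moved and 5 reversed. Both tallies include the implied totals, the pseudocount and the authors' deposited fold change, which hardly change a ratio and left all 79 the same. Under TMM scaling 39 of the 79 stayed, 36 moved and 4 reversed. Depth limits the 276 entries with under 10 reads, and the median entry had 23 reads in control and 11 with HGF.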

Other observations

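Of the tests below, those on GC content, entries with no arm, near-identical siblings, the let-7c transcript, strand and the arms of a hairpin were chosen only after the result was seen. For siblings and strand, the result needed was also made stricter after the first outcome, which had met the condition first set. The miRNAs of the next paragraph were chosen after their values were seen.

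The 5p arms of both miR-33 genes, which lie in introns of the sterol regulators SREBF2 and SREBF1, were higher with HGF. miR-33a-5p was at a log2 ratio of 0.70 (95% counting interval 0.16 to 1.24), with 66 and 55 reads, beside 0.89 for miR-33b-5p. Of their 3p arms, miR-33b-3p was at 0.69 (0.08 to 1.30) and miR-33a-3p, with 19 and 10 reads, at 0.04 (-1.23 to 1.21). Of the miR-183 cluster, miR-183-5p was at 0.59 (0.24 to 0.93) and miR-182-5p at 0.39 (0.27 to 0.51), while miR-96-5p had 9 and 2 reads, a ratio of -1.21 (-4.46 to 1.06). miR-301b-3p was at 0.55 (0.36 to 0.75). The pluripotency-associated miR-302a-3p and miR-302b-3p had 11 reads each in control and 20 and 18 with HGF, ratios of 1.82 (0.69 to 3.03) and 1.67 (0.51 to 2.90) that fall under the minimum of 50 reads. Arms and neighbours of the higher miRNAs did not all follow. miR-335-5p, from the same hairpin as miR-335-3p (1.14), was at 0.05 (-0.30 to 0.40). miR-424-5p, the neighbour of miR-503-5p (1.09) on chromosome X, was at -0.03 (-0.30 to 0.24).

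The 8 miRNAs at least 2-fold higher with HGF were mostly GC-rich entries with no arm in their name: 6 of 54 entries with no arm were 2-fold higher, against 2 of 350 with an arm. Such entries were not on the higher side alone, as 9 of the 22 miRNAs 2-fold lower carry no arm, and the median absolute log2 ratio was 0.46 without an arm and 0.26 with one. The tables argue against a general rise of entries with no arm, since all 54 had a median log2 ratio of -0.36 (bootstrap 95% interval -0.45 to -0.11). GC content stays open, as the answer depends on a threshold set from these miRNAs: the 14 with at least 73.0% GC, the lowest of the 5 GC-rich ones, had a median of 0.34 (-0.32 to 2.06), and the 22 with at least 70% had 0.14 (-0.22 to 0.81). Fragments of other structural RNA also stay open, as does an effect of HGF: 0 of the 8 hairpins shared 18 bases with an annotated structural RNA, but the annotation used holds no 18S, 28S or tRNA genes.

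Among the 12 miRNAs lowest with HGF, 6 were minor siblings. A minor sibling was at least 10 times less abundant than another miRNA of the same number and arm. Where either name carries no arm, as for miR-151b, miR-378d, miR-320c and miR-320d, number alone was matched. Siblings were grouped by name and not by sequence. The 6 met the condition first set, since the upper end of the 95% range of random sets of 12 was 3. The stricter condition was narrowly missed: all 23 minor siblings had a median of -0.36, and the lower end for sets matched on abundance was -0.37, so reads shared between siblings stay open as a source. Lower output of the let-7c transcript as the whole source for let-7c-5p (-2.05) was tested on miR-99a-5p. It was at -0.46 (-0.86 to -0.07) and did not reach the drop set for the test. However, miR-99a-5p is itself a minor sibling, so shared reads could set its ratio and the test cannot decide. miR-125b-2-3p, which is not a minor sibling, was at 0.26 (-0.08 to 0.59). This argues against such a source by that arm alone, at 75.3 CPM in control and 90.2 with HGF. An effect of HGF on these miRNAs remains untested.

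Some miRNAs from opposite strands of the same locus had nearly equal counts. miR-423-5p and miR-3184-3p, whose hairpins overlap on chromosome 17, had 4609 and 4593 reads in control and 1748 and 1754 with HGF, a share of miR-423-5p of 50.1% in control (exact 95% interval 49.1 to 51.1) and 49.9% with HGF (48.2 to 51.6). miR-103a-3p and miR-103b, looked at afterwards, had 8898 and 8905 reads in control and 4668 and 4664 with HGF. Other such pairs were unequal in control: 20472 and 1664 reads for miR-423-3p and miR-3184-5p, of the same hairpins, and 3266 and 791 for miR-24-3p and miR-3074-5p. All pairs were matched by overlap of hairpins and not of mature sequences, so the unequal pairs do not settle the question. The first pair met the condition first set, an even share in both libraries, but it is the pattern itself, so counting without regard to strand stays open, and no biological explanation was tested.

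Neighbouring hairpins might differ alike where they share a primary transcript. Over 405 pairs within 10 kb, the median absolute difference of log2 ratios was 0.31, under the 2.5% point of 1000 shufflings (0.33). This rests on chromosome 14: over 120 pairs elsewhere the difference was 0.37, above the shuffled 2.5% point of 0.30. The hypothesis of shared output therefore has weak support in the pooled pairs. Outside chromosome 14 this test gave no support, which does not argue against shared output. The pairs mix both arms of each hairpin, and the shufflings were not matched on abundance.

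Of 80 hairpins with at least 100 reads on both arms, the less abundant arm had the lower ratio in 54 (67.5%). A trend with abundance was tested by replacing the minor arm with a random miRNA of similar abundance, and 2.3% of 1000 draws gave as high a share. This lies just under the 2.5% set for the test. A run extended afterwards to 10000 draws gave 2.0%, but it includes those 1000 and is not a separate repeat. A trend with abundance is therefore only narrowly argued against. The median difference between minor and major arm was -0.12 on the log2 scale.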
